A study of Mus musculus with 18 samples.

How the data were processed

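Liver RNA from 18 mice was sequenced as 1 library per mouse. Per the labels' protocols, RNA was extracted with the RNeasy Mini Kit and libraries were made with TruSeq v2 RNA preparation; strandedness is not stated, so overlapping genes on opposite strands cannot be told apart in the counts. The submitters' processing notes name STAR 2.3.0e, HTSeq 0.5.3p9, featureCounts 1.4.3-p1, DESeq with no version and the mm10 genome, without giving the role of each tool. How these tools treated reads that match more than 1 gene is not given either, so values of close paralogs (Mup, Cyp4a, Ces1, Acaa1 and Ugt1a genes, and Ighm) are uncertain. The deposited values are raw counts per gene, in a table for the 6 males and another for the 12 females, with 1 column per mouse and no pooling. In the male table the authors also give a gene length in bases beside each gene, which was not used for any expression value.

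The male table holds 38924 Ensembl gene IDs with versions, of which 37607 (96.6%) were matched to a symbol in GENCODE M21 (GRCm38, the same build as mm10). IDs without a symbol hold 0.14% of the male counts, and 12 IDs that share a symbol were kept apart by ID. The chromosome in the table was the one in the annotation for 99.98% of matched IDs. The female table holds 23337 gene symbols and no mitochondrial gene, and 20058 names are in both tables, with 95.4% of the female and 89.9% of the male counts. Levels were never compared across the tables, since sex and table are the same split. Each column was matched to its mouse by the names in the labels, and 0 columns were left unmatched. No pair of libraries was a copy of another, and Xist and 4 Y-linked genes were checked against the stated sex.

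Each comparison used its own 6 libraries, 3 mice against 3. Separate mice are the replicates, as the labels number them; cage, litter and donor are not given, so mice that shared one would count as independent here. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 change was derived from its F statistic and is approximate. The difference of effects between males and females was fitted over the names in both tables with 1 coefficient per group, and that between treated females and recipients over the female table. CPM values use TMM-scaled library sizes.

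Before the data were examined, 42 gene lists (27 pathways and 15 cell types), the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, adjusted over all lists of the comparison, and with an estimated correlation and fry as alternatives. Camera compares a list with the other genes, while fry asks whether its genes move one way on balance. Some lists share members, so their calls are not independent. NRF2 targets and female-biased genes share some with CAR and PXR targets, and male-biased genes with major urinary proteins. A signature of the 100 genes of smallest p in each direction in treated females was tested in recipients and in males. Means of a list per mouse were compared by an exact two-sided permutation test, which cannot give less than 0.1 with 3 mice against 3. All values per mouse rest on the counting depth of its library and on mouse to mouse spread, and no interval for single libraries is given. An SD over 3 mice can fall below counting noise, and it then understates the spread.

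The rule names, per comparison, the 12 genes of largest change in each direction among those that pass with a mean of at least 1 CPM and no overlap between groups. It adds up to 3 passing members of each list and, where fewer than 10 genes pass, the 5 higher and 5 lower genes of smallest p. For the differences of effects it takes the 5 genes of smallest p in each direction. Gene models without a proper symbol are counted but not named. Members given as examples of a list are those of smallest p in the list's direction, up to 4, and this choice and the genes said to be singled out came after values were seen. Of the genes so chosen, 4 are not reported here, though they count in their lists.

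Alternatives were DESeq2 1.42.0 with its own size factors, relative log expression and upper quartile factors, no filter on low counts, a filter at a mean of 1 CPM, a fit that is not robust, all 12 libraries sharing the spread (for males over the names in both tables only), signatures of 50 and 200 genes, and leaving out each mouse in turn. Recovery was tested on simulated data of each comparison's size, with genes shifted 1.5-, 2- and 4-fold and with lists shifted 1.5-fold in 20 data sets. In them edgeR made 15 false calls of 178 in males, 15 of 160 in females and 24 of 153 in recipients, and DESeq2 made 38 of 215, 26 of 174 and 43 of 185. Mouse phenotypes and microbiota composition were not used here.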

Results

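Liver RNA was sequenced from 18 mice, 1 library per mouse, in 6 groups of 3, all at 8 weeks of age and on a diet with 45% of its energy from fat. In the first experiment, C57BL6J mice of both sexes had low-dose penicillin (LDP) from birth or none, and the high-fat diet from week 6. These were LDP males 8, 10 and 11 against control males 5, 6 and 7, and LDP females 39, 52 and 54 against control females 29, 30 and 32. In the second experiment, germ-free Swiss Webster females received at week 3 the gut microbiota of LDP females (recipients 2, 5 and 8) or of control females (recipients 1, 3 and 7), and no drug. The male libraries held 70336366 to 74418889 counts each and the 12 female libraries 17937005 to 28646168, with 19644 to 20030 and 15433 to 15893 genes counted at least once. Xist had 8045 to 19373 counts in each female library and 7 to 30 in each male library. Ddx3y had 6722 to 8594 counts in the males, Eif2s3y 3421 to 4690, Kdm5d 1598 to 1950 and Uty 1503 to 1828, and each of them had 0 in the females, so no library contradicted its stated sex. Expression values are CPM, that is, counts relative to the TMM-scaled library size, as mean ± SD over the 3 mice of a group, fold changes are on the log2 scale, and "list p" is the adjusted p of a list by camera with its preset correlation.

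The comparison of LDP with control males asks what penicillin given from birth does to gene expression in the male liver. Cholesterol synthesis stood out: all 25 measured genes of that list were higher in LDP than in control males, by a median log2 change of 0.91, and in 22 of them the groups did not overlap (list p 4.80e-38, adjusted p = 0.556 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, stood at 298 ± 98.1 CPM in LDP males and 116 ± 4.58 in controls, a 2.57-fold difference. Further down the pathway, Fdft1 (squalene synthase) stood at 97.9 ± 19.4 against 52.9 ± 4.25 and Lss at 51.3 ± 10.3 against 26.4 ± 4.32.

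Of the 25 cholesterol genes, 24 had an unadjusted p under 0.05 and 24 passed when adjusted over the list alone. By edgeR, 0 passed when adjusted over all genes, while DESeq2 called 19 and edgeR without LDP male 11 called 16. With an estimated correlation the list's p before adjustment was 0.0213. The mean of the list per mouse was 0.48 to 1.15 in LDP males and -0.15 to 0.11 in controls, with an exact two-sided permutation p of 0.1, the smallest that 3 mice against 3 allow. LDP male 11 was the lowest of the LDP males. Leaving out any 1 of the 6 mice kept the list's call, with a median of 0.77 to 1.10. Hmgcs1 was singled out after its values were seen.

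**Figure D1:**
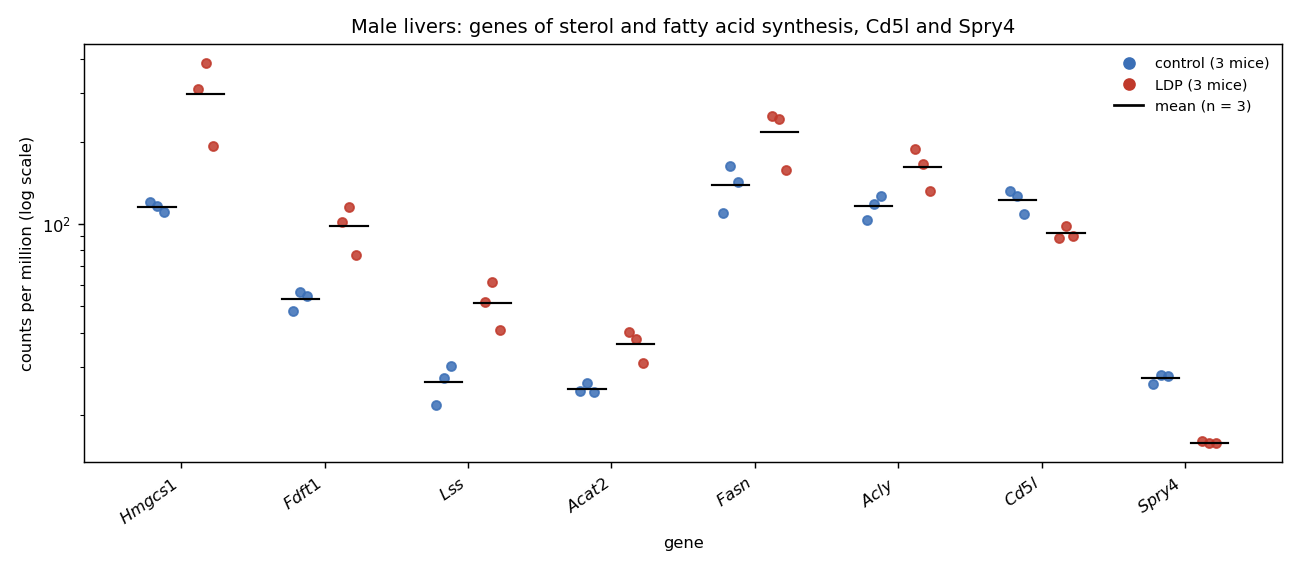
Expression of 8 genes in the livers of LDP and control males, in CPM on a log axis, 1 point per mouse with the group mean as a line. Of the cholesterol genes drawn, Hmgcs1 has means of 298 and 116 and Fdft1 of 97.9 and 52.9, while Spry4 has 15.9 and 27.2.

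Fatty acid synthesis was also higher, in 17 of 22 measured genes by a median of 0.25, with 6 at an unadjusted p under 0.05. Fatty acid synthase (Fasn) stood at 216 ± 50.5 against 139 ± 27.0, Acly, which makes cytosolic acetyl-CoA, at 162 ± 27.8 against 116 ± 11.9, and the desaturase Fads1 at 482 ± 64.0 against 372 ± 16.7. Its list p was 5.81e-04, and the adjusted p = 0.556 with an estimated correlation. The median was 0.10 without LDP male 10 and 0.42 without LDP male 11. Fatty acid oxidation and PPARA targets were lower in 34 of 36 genes by a small median of -0.18, with 2 at an unadjusted p under 0.05, Slc22a5 (30.6 ± 3.60 against 38.8 ± 4.77) and Slc25a20 (119 ± 11.8 against 144 ± 19.6), both carriers of carnitine. The list p was 4.27e-08, and the adjusted p = 0.603 with an estimated correlation. The median was -0.05 without control male 5, -0.11 without LDP male 8 and -0.28 without LDP male 11. Lipid droplet and PPARG targets were lower in 12 of 18 genes (median -0.13, list p 0.0421, adjusted p = 0.556 with an estimated correlation), among them Gpd1 (-0.44), and lost the call without LDP male 8, LDP male 11, control male 5 or control male 7 (medians -0.09, -0.09, -0.11 and -0.14) and with the filter at a mean of 1 CPM (list p 0.106).

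Markers of Kupffer cells, the resident macrophages of the liver, were lower in 12 of 13 genes by a median of -0.25. Of these, 8 had an unadjusted p under 0.05 and 6 passed when adjusted over the list alone, with 1 higher marker passing it too. Cd5l stood at 92.8 ± 5.16 against 122 ± 11.9, C1qa at 39.7 ± 1.91 against 48.2 ± 5.63 and Timd4 at 8.01 ± 0.340 against 10.3 ± 1.03. The list p was 1.46e-07, and the adjusted p = 0.556 with an estimated correlation, with a median of -0.16 without control male 5. Interferon response genes were lower in 38 of 46 (median -0.19, list p 2.12e-06, adjusted p = 0.738 with an estimated correlation), with Irf1 alone at an unadjusted p under 0.05 (21.6 ± 2.70 against 26.6 ± 2.41). That call rested on LDP male 11, without which the median was 0.01 and the list p 0.990; the median was -0.46 without LDP male 10 and -0.10 without control male 5. Monocyte and recruited macrophage markers (9 of 11 lower, median -0.26, list p 8.67e-04, adjusted p = 0.556 with an estimated correlation) had list p 0.119 and median -0.17 without LDP male 11, and median -0.86 without LDP male 10. MHC class II genes (10 of 13 lower, median -0.26, list p 0.00274, adjusted p = 0.603 with an estimated correlation) had list p 0.271 without LDP male 11 and 0.0505 without control male 5, and median -0.59 without LDP male 10. In LDP males 10 and 11 the mean of the extracellular matrix list stood far apart, at 0.64 and -0.73, and over all 6 mice that list was not called, with a median of 0.10 where the test pointed lower.

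Heat shock genes were lower in 14 of 16 (median -0.17, list p 8.88e-06, adjusted p = 0.556 with an estimated correlation), with the chaperone Hsp90aa1 at 102 ± 18.9 against 129 ± 12.2; the median was -0.11 without LDP male 8. Genes of ER stress and the amino acid response were lower in 20 of 24 (median -0.15, list p 6.22e-05, adjusted p = 0.556 with an estimated correlation), with medians of -0.07 without LDP male 8 and -0.27 without LDP male 11. Major urinary proteins, pheromone carriers made by the liver, were lower in 20 of 21 (median -0.24, list p 4.27e-08, adjusted p = 0.556 with an estimated correlation), with medians of -0.38 without LDP male 10 and -0.40 without control male 6. Mup17 stood at 1225 CPM against 1730, although reads of this near-identical family cannot be assigned to 1 member with certainty. Genes that male livers express more were lower in 18 of 20 (median -0.15, list p 5.52e-04) and genes that female livers express more were higher in 17 of 19 (median 0.32, list p 0.00214), each with adjusted p = 0.556 with an estimated correlation. Abcd2, a peroxisomal transporter on the female-biased list, stood at 44.9 ± 8.23 against 26.2 ± 5.96. The male-biased call was lost without LDP male 8 (median -0.04) and the female-biased call without LDP male 11 (list p 0.136), while the female-biased median was 0.60 without control male 7.

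Cell cycle genes were lower in 28 of 37 (median -0.17, list p 0.00418, adjusted p = 0.603 with an estimated correlation), a call lost without LDP male 11 (median -0.10) or control male 6 (-0.07), with median -0.09 without LDP male 8. Cytosolic ribosomal proteins were lower in 63 of 81 by a median of only -0.03 (list p 0.0248, adjusted p = 0.891 with an estimated correlation), lost without LDP male 10 or control male 5 (list p 0.990 and 0.922). Sinusoidal endothelial markers were higher in 13 of 14 by 0.07 (list p 0.0423, adjusted p = 0.769 with an estimated correlation), lost without LDP male 8, LDP male 11 or control male 6, the last with a median of -0.04. B and plasma cell markers were higher in 9 of 11 by 0.39 (list p 0.0486, adjusted p = 0.682 with an estimated correlation), with Ighm, the IgM heavy chain, at 5.53 ± 1.17 against 3.16 ± 0.532. That call was lost without LDP male 8, LDP male 10, control male 5 or control male 7 (medians 0.15, 0.30, 0.22 and 0.14) and with the filter at a mean of 1 CPM, which left 4 of its genes (list p 0.0889). In all, 17 of 41 lists passed with the preset correlation, 5 higher and 12 lower, and 0 with an estimated correlation or by fry, where an unadjusted p under 0.05 was found for 1 list (cholesterol synthesis) and 2 lists (also Kupffer cell markers). With the filter at a mean of 1 CPM 15 of 38 passed. The mean per mouse did not overlap between the groups for 2 of the 17 lists, cholesterol synthesis and Kupffer cell markers. Hepatocyte markers as a list were not called (median 0.02), while albumin took 7.64 ± 0.63% of all counts in LDP males and 6.36 ± 0.49% in controls, with no overlap between the groups.

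Among single genes, Spry4, an inhibitor of receptor tyrosine kinase signalling on chromosome 18 (38586247 to 38601415, GRCm38), fell by 0.78 with an approximate SE of 0.0646, from 27.2 ± 1.06 CPM in controls to 15.9 ± 0.137 in LDP males. It was the 1 gene of 15438 that passed in edgeR (adjusted p = 0.00998). The SD among LDP males lies below what counting noise alone would give at that depth, so it understates the spread. The Spry4 call was lost without LDP male 8 (adjusted p = 0.140), control male 6 (0.162) or control male 7 (0.164), at fold changes of -0.81 to -0.76 in every subset of 5 mice. It was also lost with the 12 libraries of the first experiment sharing the spread (1). That fit was limited to gene names in both tables as well, so gene set and spread changed together. The next genes did not pass by edgeR (adjusted p = 0.871 each). DESeq2 called each of those named here except Shb (0.0964). Without LDP male 11 edgeR called Erg28, Acat2, Fdft1 and Shb, and without the filter on low counts Erg28 (0.0278). Higher were Erg28, a scaffold of sterol synthesis (59.3 ± 6.31 against 40.6 ± 2.08), Acat2 (higher by 0.54), Pstpip2 (7.94 ± 0.575 against 4.96 ± 0.504), and Fdft1 of the cholesterol list. Lower were Bst2, an interferon-induced antiviral protein (72.3 ± 3.46 against 90.2 ± 4.52), Shb (31.7 ± 4.03 against 41.9 ± 2.39), Wnk4 (3.19 ± 0.705 against 5.50 ± 0.718) and Cd5l. At an unadjusted p under 0.05 there were 490 higher and 318 lower genes, 808 where chance gives 771.9, and 1625 genes (10.5%) had no overlap between groups, where chance gives 10%. DESeq2 called 38 higher and 4 lower. In simulated data of this size, edgeR found 59.7% of genes shifted 1.5-fold and 86.6% of those shifted 2-fold.

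The comparison of LDP with control females asks the same of the female liver. Genes of the extracellular matrix were higher: 22 of 24 measured, by a median of 0.53 (list p 1.26e-24, adjusted p = 0.492 with an estimated correlation). Col3a1, a fibrillar collagen, stood at 96.8 ± 11.8 CPM in LDP females and 45.2 ± 6.46 in controls, Col1a1 at 16.5 ± 3.74 against 7.13 ± 1.52, Col1a2 at 38.9 ± 6.23 against 23.0 ± 1.27 and Col6a3, of the microfibrillar collagen VI, at 15.8 ± 2.75 against 7.95 ± 1.31. Interferon response genes were higher in 47 of 47 by a median of 0.30 (list p 2.35e-22, adjusted p = 0.492 with an estimated correlation), among them the antiviral genes Ifit2 (16.6 ± 1.77 against 9.59 ± 1.32) and Rsad2 (20.2 ± 0.222 against 12.9 ± 1.79). The SD of Rsad2 among LDP females lies below counting noise at that depth and understates the spread. Fatty acid oxidation and PPARA targets were lower in 36 of 36 by a median of -0.40 (list p 3.66e-21, adjusted p = 0.492 with an estimated correlation), among them the fatty acid hydroxylase Cyp4a14, at 813 ± 109 CPM against 2009 ± 1051.

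Of the 24 matrix genes, 18 had an unadjusted p under 0.05 and 15 passed when adjusted over the list alone. By edgeR, 0 passed over all genes, and DESeq2 called 5. With an estimated correlation the list's p before adjustment was 0.0164. The mean of the list per mouse was 0.41 to 0.75 in LDP females and -0.11 to 0.13 in controls (exact two-sided permutation p of 0.1, the smallest possible). The call was kept without any 1 of the 6 mice, with a median of 0.41 to 0.61, and 12 members had an unadjusted p under 0.05 without LDP female 39. Markers of the mesothelium that covers the liver had higher means in LDP females, but none passed by edgeR (adjusted p = 0.924 for Gpm6a and 0.999 for the others) or by DESeq2. Msln stood at 3.46 ± 2.21 against 1.33 ± 0.246, Upk3b at 3.64 ± 2.03 against 1.26 ± 0.172 and Gpm6a at 4.52 ± 1.74 against 1.96 ± 0.176. With overlap between the groups, Lrrn4 stood at 1.07 ± 0.906 against 0.434 ± 0.264 and Krt19, also a bile duct marker, at 1.15 ± 0.531 against 0.781 ± 0.0289. These 5 were singled out after the matrix result was seen. Their mean was highest in LDP female 39, at 1.83, with 0.77 and 0.42 in the other LDP females. Stellate cell markers were higher in 9 of 12 by 0.19 (list p 0.00448, adjusted p = 0.607 with an estimated correlation), lost without LDP female 54 or control female 29 (medians 0.07 and 0.05) and at 0.30 without LDP female 52.

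**Figure D2:**
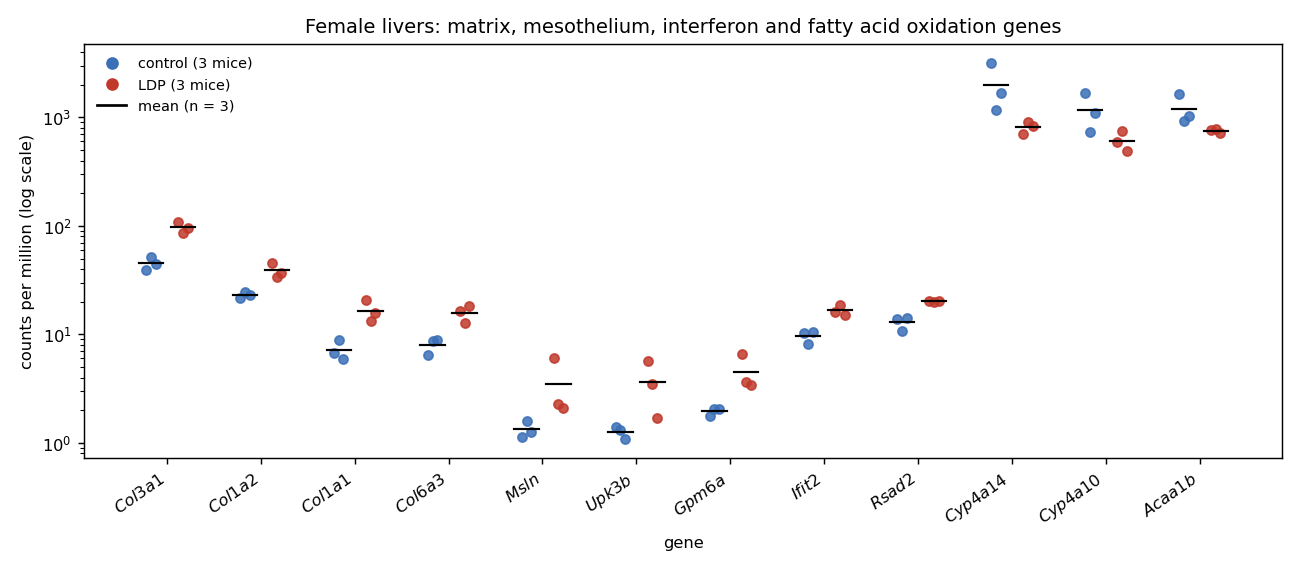
Expression of 12 genes in the livers of LDP and control females, in CPM on a log axis, 1 point per mouse with the group mean as a line. Col3a1 has means of 96.8 and 45.2, and Msln, Upk3b and Gpm6a have 1 LDP female well above the other mice.

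Of the interferon genes, 19 had an unadjusted p under 0.05 and 2 passed when adjusted over the list alone. The median was 0.24 to 0.40 without any 1 mouse. The mean of the list per mouse, 0.16 to 0.46 in LDP females, overlapped that of controls, -0.18 to 0.21 (exact two-sided permutation p of 0.2). Of the fatty acid oxidation genes, 13 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Ech1, of peroxisomal and mitochondrial oxidation, stood at 329 ± 10.8 against 459 ± 105. Cyp4a10 (607 ± 129 against 1160 ± 474) and Acaa1b (753 ± 33.6 against 1191 ± 387) have close paralogs that can share reads. Without control female 29, the highest of the 6 mice, the median was -0.20. Lipid droplet and PPARG targets were lower in 13 of 18 by -0.21 (list p 0.0129, adjusted p = 0.607 with an estimated correlation), with Plin5, a droplet coat protein, at 51.9 ± 7.74 against 76.0 ± 13.5, and lost the call without LDP female 52, LDP female 54 or control female 29 (medians -0.19, -0.21 and -0.07). Oxidative phosphorylation genes were lower in 57 of 75 by only -0.06 (list p 0.00659, adjusted p = 0.944 with an estimated correlation), lost without LDP female 54 or control female 29 (list p 0.944 and 0.788), with a median of -0.10 without control female 30.

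Monocyte and recruited macrophage markers were higher in 10 of 11 by 0.29 (list p 7.03e-05, adjusted p = 0.492 with an estimated correlation), and by 0.50 without control female 29. Genes of bacterial sensing and inflammatory cytokines were higher in 21 of 28 by 0.17 (list p 0.00919, adjusted p = 0.607 with an estimated correlation), with the chemokines Ccl2 (1.10) and Cxcl1 (0.97) at an unadjusted p under 0.05. Acute phase genes were higher in 22 of 32 by 0.16 (list p 0.0358, adjusted p = 0.627 with an estimated correlation), with Hamp, the iron hormone hepcidin, at 580 ± 163 against 368 ± 82.8. Immediate early genes were higher in 11 of 20 by 0.24 (list p 0.0358, adjusted p = 0.607 with an estimated correlation), with Atf3 at 2.71 ± 1.15 against 0.808 ± 0.188. The bacterial sensing call was lost without LDP female 52, LDP female 54 or control female 30 (medians 0.17, 0.13 and 0.08). The acute phase call was lost without LDP female 52 or control female 30 (0.02 and 0.04), with 0.07 without LDP female 54. The immediate early call was lost without LDP female 39, LDP female 54, control female 30 or control female 32 (0.23, 0.07, 0.15 and 0.23).

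Periportal hepatocyte markers were higher in 11 of 12 by 0.26 (list p 0.00111, adjusted p = 0.492 with an estimated correlation), with Cyp2f2 at 850 ± 50.2 against 661 ± 46.3, and by 0.16 without LDP female 54 and 0.15 without control female 29. Pericentral markers were lower in 11 of 14 by -0.19 (list p 0.0261, adjusted p = 0.764 with an estimated correlation). That call was lost without LDP female 54, where the median was 0.07, and without control female 29 (-0.13), while the median was -0.40 without LDP female 39. Cell cycle genes were lower in 33 of 37 by -0.24 (list p 1.37e-05, adjusted p = 0.607 with an estimated correlation), lost without LDP female 39 (-0.06), with -0.40 without LDP female 54 and -0.12 without control female 29. Major urinary proteins were lower in 14 of 15 by -0.52 (list p 1.33e-04, adjusted p = 0.607 with an estimated correlation), lost without LDP female 54 (-0.29) and at -0.30 without control female 29. Of these members 0 had an unadjusted p under 0.05 and 0 separated the groups. Summed over the family, whose reads cannot be assigned to 1 member with certainty, the level was nearly equal, at 3730 CPM against 3805. In all, 14 of 37 lists passed, 8 higher and 6 lower, and 0 with an estimated correlation or by fry, where an unadjusted p under 0.05 was found for 3 lists (extracellular matrix, interferon response and monocyte markers) and 2 lists (the former pair). The mean per mouse did not overlap between the groups for 2 of the 14 lists, the extracellular matrix and fatty acid oxidation. Cholesterol synthesis (median 0.01), Kupffer cell (0.01), sinusoidal endothelial (-0.06) and hepatocyte markers (-0.02) were not called.

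No single gene passed in females: edgeR called 0 of 12914, with 347 higher and 235 lower at an unadjusted p under 0.05 (582 where chance gives 645.7), and DESeq2 called 12 higher and 2 lower. Col3a1 came nearest (1.10, approximate SE 0.134, adjusted p = 0.206) and passed without the filter on low counts (adjusted p = 0.0162). The other genes of smallest p were the collagens and Ifit2 given above and, lower in LDP females, Gja4, a gap junction protein of vessel endothelium (4.03 ± 0.914 against 9.89 ± 2.64, adjusted p = 0.591), all called by DESeq2, and, also lower but not called by it, Rufy4 (0.875 ± 0.172 against 2.10 ± 0.252), Tmc7 (7.43 ± 1.70 against 12.8 ± 0.896), Aifm3 (2.50 ± 0.180 against 4.16 ± 0.496) and the ephrin receptor Epha2 (12.8 ± 1.86 against 18.6 ± 1.52). Groups did not overlap in 1178 genes (9.12%), where chance gives 10%. In simulated data of this size, edgeR found 31.3% of genes shifted 1.5-fold and 88.1% of those shifted 2-fold.

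The comparison of recipients asks what the microbiota of LDP females does in the liver of mice that never had the drug. By camera with the preset correlation, fatty acid oxidation, cholesterol synthesis and CAR and PXR target lists were higher in recipients of LDP microbiota and the acute phase list was lower, but with an estimated correlation none of them passed (adjusted p = 0.774, 0.760, 0.638 and 0.638). Fatty acid oxidation and PPARA targets were higher in 33 of 36 by a median of 0.23, among them Hadhb (0.42), of mitochondrial oxidation, and Acaa1b (1312 ± 338 against 805 ± 117). Cholesterol synthesis was higher in 23 of 25 by 0.50, with Fdps, which makes farnesyl diphosphate and overlaps another gene model on its strand, at 14.3 ± 7.35 against 5.56 ± 1.42 and Pmvk higher by 0.72. CAR and PXR targets, the enzymes that handle foreign compounds, were higher in 32 of 39 by 0.15, with Aldh1a7 at 46.5 ± 11.3 against 22.2 ± 3.77 and Gsta4 at 98.3 ± 12.9 against 69.9 ± 2.08. Acute phase genes were lower in 25 of 32 by -0.20, with Lcn2 at 18.8 ± 6.24 against 56.0 ± 14.9, Fgl1 at 639 ± 93.6 against 1146 ± 357 and Il6ra, the IL-6 receptor, at 79.4 ± 10.2 against 115 ± 33.7.

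The list p for CAR and PXR targets was 4.83e-05. Of its members, 9 higher ones had an unadjusted p under 0.05 and 7 of them passed when adjusted over the list alone, with 1 lower member doing both. The list's mean per mouse did not overlap between the groups (0.20 to 0.33 against -0.09 to 0.13), nor did that of the acute phase genes (-0.36 to -0.14 against -0.11 to 0.06), each with an exact two-sided permutation p of 0.1, the smallest possible. For acute phase genes the list p was 0.00149. Of these, 7 members had an unadjusted p under 0.05 and 1 passed when adjusted over the list alone. The CAR and PXR median was 0.22 without LDP-microbiota recipient 8 and 0.24 without control-microbiota recipient 1, and the acute phase median was -0.11 without control-microbiota recipient 3. For cholesterol synthesis the list p was 3.68e-08; 8 members had an unadjusted p under 0.05, and the median was 0.31 without LDP-microbiota recipient 5. For fatty acid oxidation the list p was 3.05e-08; 8 members had an unadjusted p under 0.05. Its median was 0.35 without LDP-microbiota recipient 2, 0.13 without control-microbiota recipient 1, 0.14 without control-microbiota recipient 3 and 0.45 without control-microbiota recipient 7, a control whose own mean on this list, 0.52, was near the highest LDP-microbiota recipient, 0.53.

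**Figure D3:**
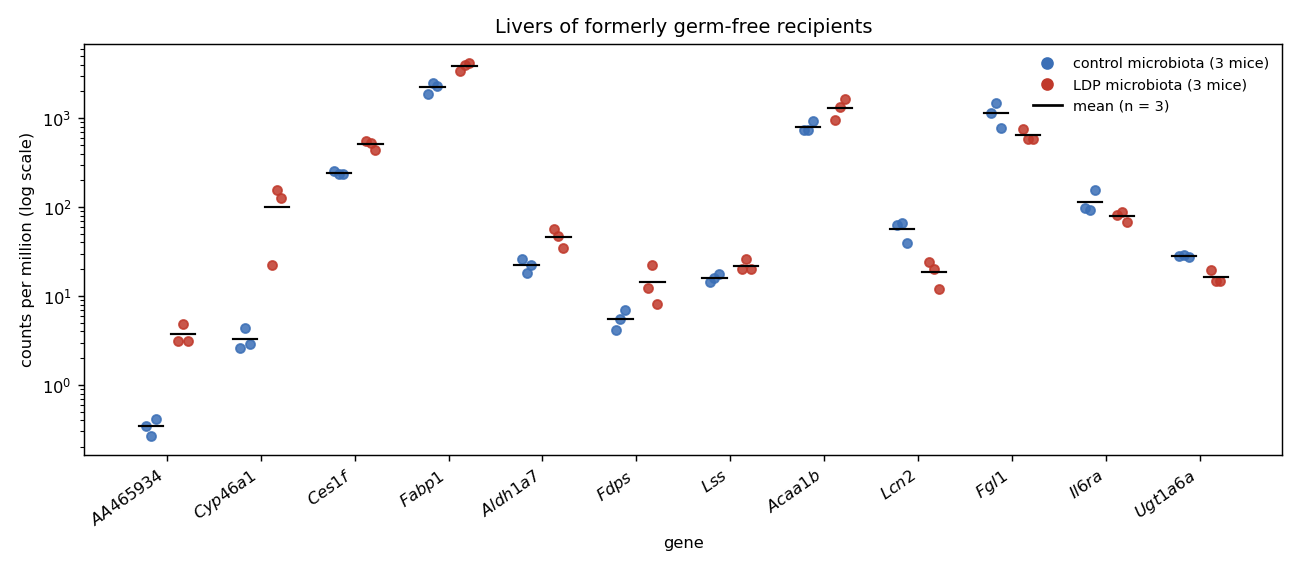
Expression of 12 genes in the livers of germ-free mice given LDP or control microbiota, in CPM on a log axis, 1 point per mouse with the group mean as a line. AA465934 has means of 3.73 and 0.344, Ces1f of 506 and 241 and Lcn2 of 18.8 and 56.0.

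Oxidative phosphorylation genes were higher in 68 of 75 by 0.19 (list p 2.15e-10, adjusted p = 0.774 with an estimated correlation), with the complex I subunit Ndufb10 at 106 ± 17.4 against 84.4 ± 0.287. The SD of Ndufb10 among control-microbiota recipients lies below counting noise at that depth and understates the spread. Cytosolic ribosomal proteins were higher in 71 of 78 by 0.18 (list p 5.12e-08, adjusted p = 0.774 with an estimated correlation). Both leaned on LDP-microbiota recipient 8, without which the medians were 0.07 and 0.03 and the ribosomal call was lost, and the ribosomal median was 0.26 without LDP-microbiota recipient 2. Cell cycle genes were higher in 23 of 25 by 0.29 (list p 1.40e-04, adjusted p = 0.760 with an estimated correlation), among them the mitotic kinase Cdk1 (1.33), with medians of 0.14 without LDP-microbiota recipient 5, 0.50 without LDP-microbiota recipient 8 and 0.46 without control-microbiota recipient 7. NRF2 targets, of the oxidant response, were higher in 13 of 18 by 0.11 (list p 0.0109, adjusted p = 0.638 with an estimated correlation), with Gstm1, also on the CAR and PXR list, higher by 0.39, and lost the call without LDP-microbiota recipient 5 (0.09). Female-biased genes were higher in 19 of 26 by 0.18 (list p 0.0213, adjusted p = 0.760 with an estimated correlation), with the oxidase Hao2 higher by 0.41. That call was lost without LDP-microbiota recipient 2, LDP-microbiota recipient 5 or control-microbiota recipient 3 (0.16, 0.12 and 0.21), with 0.32 without control-microbiota recipient 7. Targets of AHR, the receptor for aryl compounds, were lower in 6 of 8 by -0.25 (list p 0.0236, adjusted p = 0.760 with an estimated correlation), with Ugt1a6b at 14.7 ± 3.05 against 22.4 ± 1.72. Ugt1a6a and Ugt1a6b share exons, so they are not independent members. The AHR call was lost without LDP-microbiota recipient 8, control-microbiota recipient 1 or control-microbiota recipient 7 (-0.11, -0.16 and -0.25).

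Heat shock genes were higher in 12 of 16 by 0.13 (list p 0.0236, adjusted p = 0.785 with an estimated correlation) and lipid droplet and PPARG targets in 11 of 17 by 0.12 (list p 0.0298, adjusted p = 0.774 with an estimated correlation). Both calls were lost without LDP-microbiota recipient 5, LDP-microbiota recipient 8, control-microbiota recipient 1 or control-microbiota recipient 3 (heat shock medians 0.11, 0.06, -0.05 and -0.06, lipid droplet medians 0.01, 0.04, 0.03 and 0.06). Without control-microbiota recipient 7 those medians were 0.45 and 0.47, and the heat shock median was 0.26 without LDP-microbiota recipient 2. Adipocyte markers were 3 genes, 2 of them higher, with a median of 0.56 (list p 0.0236, adjusted p = 0.638 with an estimated correlation), and Car3, a carbonic anhydrase that hepatocytes also express, stood at 2379 ± 204 against 1014 ± 346. Without LDP-microbiota recipient 5 that call was lost (0.37). In all, 13 of 38 lists passed, 11 higher and 2 lower, and 0 with an estimated correlation or by fry, where an unadjusted p under 0.05 was found for 0 lists and 1 list (adipocyte markers). The mean per mouse did not overlap between the groups for 3 of the 13 lists, CAR and PXR targets, acute phase genes and adipocyte markers. The fatty acid synthesis, lipoprotein, bile acid, extracellular matrix, interferon and Kupffer cell lists were not called, and male-biased genes had a median of -0.02 while the test pointed higher, without a call.

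Among single genes, AA465934, a processed transcript on chromosome 11 (83291699 to 83294632, GRCm38) that holds the small nucleolar RNA gene Snord7 on the same strand, rose by 3.41 (approximate SE 0.322), at 3.73 ± 1.01 CPM against 0.344 ± 0.0740. It was the 1 gene of 12780 that passed in edgeR (adjusted p = 0.0271), and of the 6 fits that leave out 1 mouse it kept the call only without LDP-microbiota recipient 8 (0.0372). Without LDP-microbiota recipients 2 and 5 the adjusted p was 0.0584 and 0.0927, and without control-microbiota recipients 1, 3 and 7 it was 0.239, 0.118 and 0.0659, with fold changes of 3.18 to 3.58. Ces1f, a liver carboxylesterase with close paralogs, came next at 506 ± 62.4 against 241 ± 11.6 (adjusted p = 0.104). It passed by DESeq2 (7.78e-10), without the filter on low counts (0.0228), with the 12 female-table libraries sharing the spread (0.0110) and without LDP-microbiota recipient 8 (0.0372). Other genes of smallest p did not pass by edgeR. DESeq2 called each of them except Adarb1, Plxna4 and Art4, and Thnsl2 also passed with the 12 libraries sharing the spread (0.0459). Higher were Fabp1, the fatty acid binding protein of hepatocytes (3875 ± 415 against 2215 ± 305), Thnsl2 (61.8 ± 2.98 against 36.1 ± 2.66) and Car1 (12.5 ± 0.741 against 6.68 ± 1.29), and lower were Ugt1a6a (16.3 ± 2.65 against 28.1 ± 0.702), Lcn2, Adarb1 (-0.70), Plxna4 (1.65 ± 0.165 against 3.50 ± 0.687) and Art4 (1.52 ± 0.392 against 3.41 ± 0.482). Cyp46a1, a cholesterol hydroxylase singled out after its values were seen, stood at 101 ± 70.0 against 3.29 ± 0.951 and did not pass by edgeR (adjusted p = 0.777). It passed by DESeq2 (1.10e-06) and by edgeR without LDP-microbiota recipient 2 (adjusted p = 0.000231, fold change 5.41). At an unadjusted p under 0.05 there were 287 higher and 366 lower genes (653 where chance gives 639), DESeq2 called 14 and 6, and 1493 genes (11.7%) had no overlap, where chance gives 10%. In simulated data of this size, edgeR found 22.4% of genes shifted 1.5-fold and 74.6% of those shifted 2-fold.

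**Figure D4:**
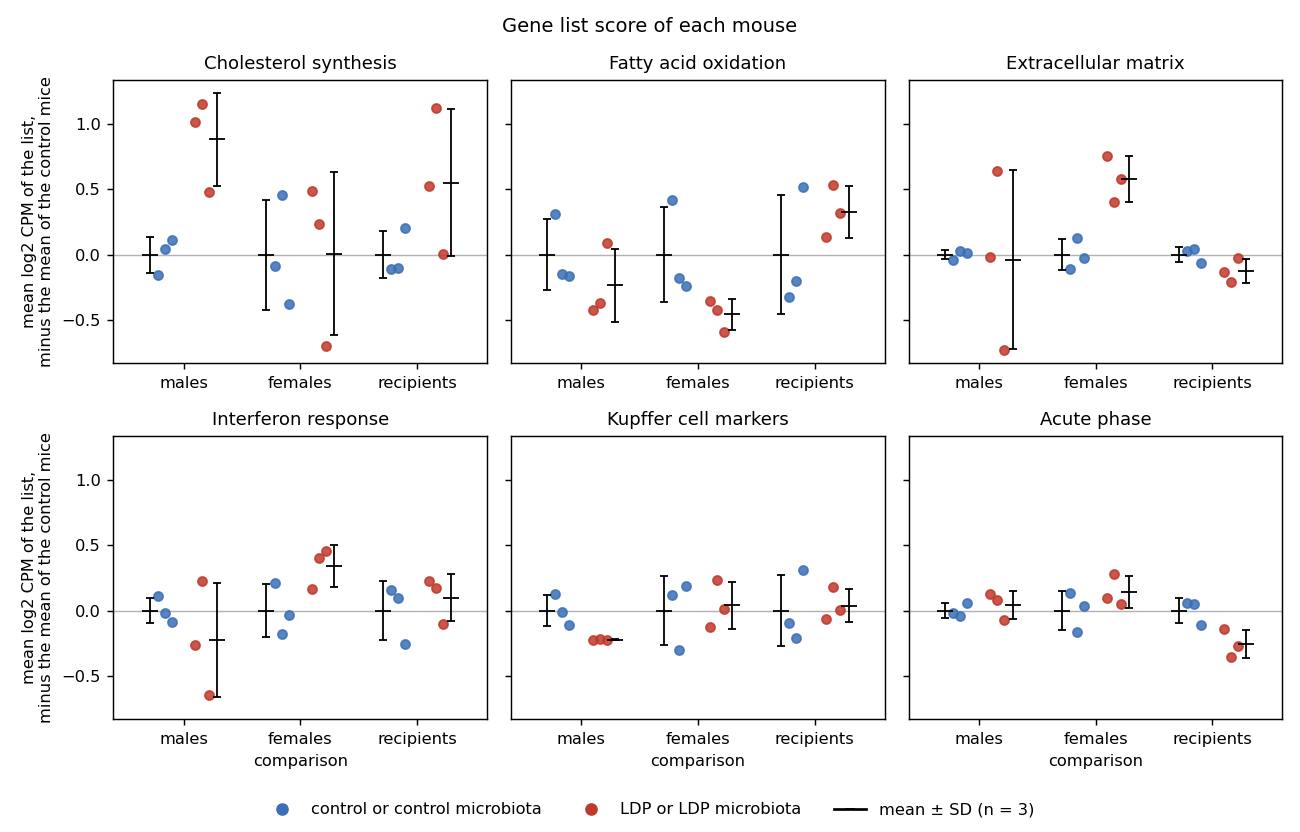
Mean log2 level of the genes of 6 lists in each mouse, relative to the control mean of its comparison, with group means and SD. Cholesterol synthesis is higher in LDP males (0.48 to 1.15), the extracellular matrix in LDP females (0.41 to 0.75), and acute phase genes are lower in LDP-microbiota recipients (-0.36 to -0.14).

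Whether penicillin acted differently in males and females was tested as a difference of effects, since sex and count table are the same split. By edgeR, 0 of 12747 genes passed, with 345 at an unadjusted p under 0.05 where chance gives 637, and DESeq2 called 0, with 368. Of the genes of smallest p, Atf3 was lower in LDP males and higher in LDP females (-0.86 against 1.76), as were Rsad2 (-0.48 against 0.65) and Cmpk2 (-0.55 against 0.66). S1pr5 differed by 1.23, Hist2h2be by 0.91, Parp16 by 0.78 and Slc12a7 by 0.42 towards males, and Pik3ap1 by -0.54 and Rpusd4 by -0.50 towards females (adjusted p of 1 each after rounding). As lists, cholesterol synthesis (median 0.90 in males, 0.01 in females) and interferon response (-0.19 and 0.30) had the smallest p with the preset correlation, with list p of 3.98e-19 and 8.08e-22 and, for both, adjusted p = 0.491 with an estimated correlation. The median difference in interferon response was -0.52, and -0.31 without LDP male 11.

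Between treated females and recipients, edgeR called 0 of 13295 genes as different in effect, with 790 at an unadjusted p under 0.05 where chance gives 665, and DESeq2 called 14, with 777, among them each gene named here. Ces1f came nearest, with -0.25 in treated females and 1.08 in recipients (adjusted p = 0.0933). Col6a3 (0.98 against -0.48, adjusted p = 0.225), Col1a1 (1.21 against -0.20) and Emp1 (1.26 against -1.14) were higher in LDP females and lower in recipients of LDP microbiota, and Acaa1b (-0.67 against 0.72) was the reverse. AA465934 differed by -2.95 (adjusted p = 0.340), Gja4 by -1.52, Fbxo44 by -4.25, Art4 by 1.93 and Ugt1a6a by 0.80. As lists, fatty acid oxidation (-0.40 in females, 0.24 in recipients) and the extracellular matrix (0.52 and -0.05) had the smallest p with the preset correlation, with list p of 1.09e-18 and 4.56e-13 and adjusted p = 0.444 and adjusted p = 0.331 with an estimated correlation. Strain, colonisation history and drug differ together between these experiments. The start of the high-fat diet, week 6 in the first experiment, is not given for the recipients and may differ as well.

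The genes of smallest p in females, none of which passed there by edgeR, showed no common direction in recipients by fry. Of the 100 higher and 100 lower genes of smallest p in the female comparison, 181 were measured in recipients and 89 had the same sign (49.2%), with a difference of -0.05 between the mean change of the former and that of the latter and a fry p of 0.776. In males 132 of 180 had the same sign (73.3%) with a difference of 0.29 and a fry p of 0.652. The 100 lower genes were also lower in males by camera (p of 8.99e-05, and 0.312 with an estimated correlation), but not without LDP male 10 (p of 0.187). Without that mouse the 100 higher genes were lower in males (a mean of -0.10, p of 0.000139 by camera with the preset correlation, the only one used for that fit) and the difference was -0.07. Over all males, the higher genes had a camera p of 0.108 with the preset and 0.756 with an estimated correlation. Across genes, which are not independent replicates, the fold changes of females and males had a Pearson correlation of 0.22 and a Spearman correlation of 0.19, and those of females and recipients -0.07 and -0.12. Those of males and recipients were -0.02 and -0.08. Males and recipients shared 25 genes higher at an unadjusted p under 0.05, where 8.03 would be shared by chance, among them Fdps, Pmvk, Mvk, Lss, Fdft1 and Nsdhl of cholesterol synthesis. In turn, 25 genes higher in LDP males were lower in recipients of LDP microbiota, where chance gives 10.1. They shared 6 lower genes, Spry4 among them, where chance gives 6.92. Females and males shared 17 higher and 12 lower genes (9.77 and 4.53 by chance), and females and recipients 11 and 3 (7.03 and 6.49). Of the genes higher in LDP females, 17 were lower in recipients of LDP microbiota (9.03 by chance), and 7 lower ones were higher there (5.05). In males the opposite counts were 4 and 4 (6.81 and 6.50). No control library served more than 1 of these comparisons. The chance counts of shared genes take genes as independent and carry no spread. Cholesterol synthesis genes had an estimated correlation of 0.63 in males and 0.60 in recipients, so 1 such list can raise the shared count. With LDP-microbiota recipients 2 and 5 and control-microbiota recipient 7 set against the other recipients, that list's median was 0.53 in absolute size, above the real 0.50.

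The list calls carry a common limit. In simulated data where each mouse had its own deviation of 0.2 log2 shared within a list, the preset correlation called 49.1% of unchanged lists in males, 46.9% in females and 39.2% in recipients. With the estimated correlation it was 0% in all 3, but a list truly shifted 1.5-fold was then found in 2, 1 and 1 of 20 data sets. Without such a deviation the preset correlation called 0.50%, 0.28% and 0.27% of unchanged lists and the estimated correlation 0%. The latter found the shifted list in 19, 16 and 19 of 20. The 0.2, an SD, was a chosen setting and not an estimate from these mice. Some lists spread more between mice of 1 group, as the matrix list did in LDP males. The share of false calls could be higher for such lists.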

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

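The tests of lists between comparisons and the test of a lower hepatocyte share were chosen only after the results they bear on were seen; the tests of clock, feeding state and tissue markers used lists chosen after the main results but before their own values. What drew attention in each case is that a list's effect differed between comparisons by camera with the preset correlation. None of the 25 differences passed with an estimated correlation, where the adjusted p ran from 0.286 to 0.759. Values are the median over the list's genes of the first effect less the second, on the log2 scale.

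Males less females differed by 0.85 in cholesterol synthesis, -0.52 in interferon response, -0.63 in monocyte and recruited macrophage markers and -0.47 in the extracellular matrix. Smaller differences were 0.16 in fatty acid oxidation, -0.29 in bacterial sensing and inflammatory cytokines, -0.25 in Kupffer cell and 0.10 in sinusoidal endothelial markers. Insulin and growth hormone signalling differed by -0.31, immediate early genes by -0.24 and fatty acid synthesis by 0.19. Females less recipients differed by -0.66 in fatty acid oxidation, 0.61 in the extracellular matrix, -0.62 in the cell cycle, -0.52 in cholesterol synthesis and 0.52 in monocyte and recruited macrophage markers. Oxidative phosphorylation differed by -0.24, cytosolic ribosomal proteins by -0.23, interferon response by 0.28, acute phase genes by 0.29 and CAR and PXR targets by -0.21. Lipid droplet genes differed by -0.28, heat shock genes by -0.30, pericentral markers by -0.35 and bacterial sensing by 0.27.

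Leaving out 1 mouse at a time kept the sign of each of these medians, but 49 of the 300 fits lost the call, over 13 of the 25 differences. For males against females those were fatty acid oxidation, fatty acid synthesis, insulin and growth hormone signalling, Kupffer cell and sinusoidal endothelial markers and immediate early genes. For females against recipients they were cholesterol synthesis, cytosolic ribosomal proteins, CAR and PXR targets, lipid droplet genes, heat shock genes, pericentral markers and bacterial sensing. Without LDP male 11 the differences between males and females were -0.31 in interferon response and -0.18 in the extracellular matrix.

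Cholesterol synthesis was higher in LDP males, with a list median of 0.91. The tables argue against a bias of gene length or GC content, since with that trend taken off the median was 0.904. Another feeding state at collection stays open: genes raised by feeding less genes raised by fasting came to 0.695, but per mouse the LDP males (0.25 to 1.19) overlapped the controls (-0.82 to 0.56), so it cannot be told apart from an effect of the drug. Another time of day cannot be told apart either, with the evening less the morning arm of the clock at 0.235 and control males spread from -0.99 to 0.55. An effect of penicillin, which the design names, may be the source and was not tested apart from these, and the 10 splits of the mice are too few for a share under 0.05 (as large in 1, the real one at 0.91, highest other 0.77).

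Extracellular matrix genes were higher in LDP females, with a list median of 0.53. The tables argue against gene length or GC content (0.568 with the trend taken off). For a lower share of hepatocytes, pooled markers of sinusoidal endothelium, Kupffer cells and stellate cells had a median of 0.0124. The lower quartile of the matrix genes was 0.36, so these markers as a pool did not rise with the matrix genes. That test was set after the lists had been seen, and stellate markers alone were higher by 0.19, so it does not settle the question. More capsule or portal tract tissue in the sampled pieces is a candidate explanation: 22 markers of vessel wall, mesothelium and portal fibroblasts had a pooled median of 0.478. By tissue, mesothelium stood at 1.34 and portal fibroblasts at 0.48 but smooth muscle at -0.20. Members of the matrix list were taken out of the pool but not out of these medians by tissue, which are thus not parts of the pooled value. Of the 22 markers 1, Krt19, is also on the bile duct list, most are low in whole liver (Msln 3.46 ± 2.21 CPM in LDP females), and the more abundant Gsn stood at 47.9 ± 20.5 against 25.5 ± 3.52 while Mylk and Gas6 did not rise. An effect of penicillin on the matrix itself stays open and untested, and the 10 splits are too few for a share under 0.05 (as large in 1, the real one at 0.53, highest other 0.37).

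Fatty acid oxidation genes were lower in LDP females and higher in recipients of LDP microbiota. A bias of length or GC content is argued against by a difference of -0.552 with those trends taken off, at -0.39 in females and 0.16 in recipients. A library that stands apart stays open: the sign of the median was kept in 12 of 12 fits without 1 mouse, but the share left fell to 0.505 without control female 29, and these shares had an SD of 0.426. The splits are too few for a share under 0.05, with as large a median in 1 of 10 for females (real size 0.40, highest other 0.37) and in 4 of 10 for recipients (real 0.23, highest other 0.41). Drug, strain and colonisation history differ between the experiments and could each lie behind the contrast, which was not tested further. Time on the high-fat diet may differ too, since its start, week 6 in the first experiment, is not given for the recipients.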

How the results depend on the processing

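The tests of the members of called lists, of list differences and of genes singled out were chosen only after results were seen; the other alternatives were planned. Scaling by relative log expression or upper quartile factors and the fit that is not robust kept every count of called genes. Under other processing 818 values of named genes kept direction and side of the threshold, with 38 newly passing, 33 of them by DESeq2, and 1 lost. Only Spry4 and AA465934 passed in the main fits. For the other named genes, keeping the side means only that they still did not pass, which says little about robustness. With DESeq2 the counts of called genes were 42 in males, 14 in females, 20 in recipients and 14 for females against recipients. Without the filter on low counts they were 2 (Spry4 and Erg28), 1 (Col3a1) and 2 (AA465934 and Ces1f). With 12 libraries sharing the spread they were 0 in males, where the fit was also limited to gene names in both tables, and 3 in recipients (AA465934, Ces1f and Thnsl2). With an estimated correlation 0 lists passed in males, 0 in females and 0 in recipients, and by fry 0, 0 and 0. The cause was not tested in these cases.

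Leaving out 1 mouse at a time gave 0 to 66 genes in males (66 without LDP male 11, 2, Spry4 and Fabp5, without LDP male 10, 0 without LDP male 8, control male 6 or control male 7), 0 to 1 in females (A1bg without LDP female 39) and 0 to 4 in recipients (AA465934, Ces1f, Alas1 and Gabra3 without LDP-microbiota recipient 8, Cyp46a1 without LDP-microbiota recipient 2, Socs2 without control-microbiota recipient 3, Capn3 without control-microbiota recipient 7, 0 without LDP-microbiota recipient 5 or control-microbiota recipient 1). It gave 0 to 1 for males against females (Cmpk2 without LDP male 10) and 0 to 3 for females against recipients (Ces1f, Fbxo44 and Gabra3 without LDP-microbiota recipient 8, Capn3 and Hhip without control-microbiota recipient 7, Ces1f without LDP female 39, Cyp46a1 without LDP-microbiota recipient 2). The genes named here outside the rule were chosen after their values were seen. The female signature in recipients, -0.05, was 0.0435 with 50 and 0.0235 with 200 genes per direction, and -0.26 to 0.0528 without 1 mouse. Its higher genes alone gave 0.0379 and 0.0148, and -0.20 to 0.0469, and its lower genes -0.0895 to 0.24. In males the signature was -0.0661 (without LDP male 10) to 0.64 (without LDP male 11), and its higher genes -0.10 to 0.41. List medians that changed sign without 1 mouse ran from -0.46 to 0.0111 for interferon response, -0.0624 to 0.00337 for ribosomal proteins and -0.0440 to 0.14 for sinusoidal endothelium in males. They ran from -0.10 to 0.00192 for oxidative phosphorylation and -0.40 to 0.0668 for pericentral markers in females, and from -0.0570 to 0.45 for heat shock in recipients.

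No paired analysis was possible because the groups compared hold separate mice, and the labels give no cage, litter or donor that would link them. Depth limits genes of few counts, more so in the female table.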

Other observations

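The test of smooth muscle markers was chosen only after its result was seen, and the counts of splits were planned. Other splits of the 6 mice of each comparison are too few for a share under 0.05. In males, 4 of 10 splits called as many genes by edgeR (real 1, highest other 7), 4 by DESeq2 (42 and 146), and 3 called as many lists (17 and 23). In females it was 5 by DESeq2 (14 and 66) and 6 for lists (14 and 19), and in recipients 6 by edgeR (1 and 6), 4 by DESeq2 (20 and 68) and 6 for lists (13 and 18). The female signature had as large a score in 6 of 10 splits of the males (0.29 and 0.75) and 9 of 10 of the recipients (0.05 and 0.40). For edgeR in females (10 of 10 splits, real 0, highest other 0) and both differences of effects (100 of 100 splits, real 0, highest other 4) every split gives at least as many genes as the real one by construction, so these counts say nothing about chance.

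Some splits called several times the real count by DESeq2, which may point to a structure of the samples that was not tested: 146 genes for LDP males 8 and 10 with control male 6 and 121 with control male 7 in its place, 66 for LDP females 39 and 52 with control female 32, and 68 for LDP-microbiota recipient 2 with control-microbiota recipients 1 and 3, each against the other 3 mice. Smooth muscle markers, a list chosen after the main results were seen, were lower in LDP-microbiota recipients (-0.71 to -0.24) than in control-microbiota recipients (-0.04 to 0.04), with an exact two-sided permutation p of 0.1, the smallest possible.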
